A study of Cucumis sativus with 12 samples.

How the data were processed

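Leaf RNA of cucumber seedlings was extracted with TRIzol and sequenced on an Illumina HiSeq instrument, per the labels' protocols, in 12 libraries: 3 from untreated seedlings at 0 h and 3 each after 2, 6 and 12 h of chilling in the dark at an air temperature of 6 °C. The labels call the 3 libraries of a time point independent biological replicates. The submitters' processing notes name Bowtie2 2.2.3, TopHat2 2.0.12 and DESeq 1.10.1. The read counter, the genome build and the annotation were not given in the sources used here.

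The authors deposited 3 tables, 1 per chilled time point against 0 h, that hold only genes passing their filter: in each table the smallest absolute log2 ratio was above 1 and the largest FDR under 0.001. Per the file headers, each entry has a gene model, its length (a coding length, since all lengths are multiples of 3), the mean read count of each group, a normalized mean, a log2 ratio, a p-value, an FDR and a description of the best database hit. Multiplied by 3, the mean read counts at 0 h are whole in 100% of entries (tolerance 1e-06), as sums of raw counts over 3 libraries are. The deposited normalized means are a signal on the scale of counts divided by size factors, and their log2 of chilled over 0 h gives the authors' log2 ratio exactly. In the median gene a normalized mean is 1.00 times the read mean at 0 h and 0.988 times at 2 h, 0.945 and 1.05 times in the 6 h table, and 0.951 and 1.04 times in the 12 h table, so 0 h levels are not on quite the same scale in the 3 tables, and levels were compared only within a table unless stated. A mean of 0 was written by the authors as 0.001, which sets 3 log2 ratios beyond 10 in size at 6 h and 26 at 12 h, and such ratios are not printed. For these genes the fold is given with 3 reads over the group as the floor, and the limit of the counting interval can lie below it.

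The deposited p-value and FDR of each gene come from the authors' test, taken to be DESeq's from the processing notes. Since an FDR is the p-value times the number of genes tested over its rank, the columns give the number of genes tested, 20250 at 2 h, 20290 at 6 h and 20368 at 12 h, with 98.8%, 96.8% and 96.6% of entries giving a whole rank (tolerance 0.001). By the rank of the largest listed p-value, 1594, 3302 and 5572 genes had a p-value at or below it, and 1508, 2572 and 3799 of these were not listed, having changed by less than 2-fold. Values of single libraries were not analysed here. There is therefore no new test per gene, no standard deviation, no replicate-to-replicate check and no depth per library: the sums of listed genes are not library depths. The p-values rest on the spread as the authors' test estimated it, and do not measure it. A standard error of the log2 ratio back-calculated from the p-value by a normal approximation had a median of 0.366 at 12 h for genes with a mean under 100 reads and 0.0660 for genes with 1000 or more, which shows how precision grows with reads and is only approximate.

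Intervals printed beside log2 ratios of genes with few reads are 95% Clopper-Pearson intervals of the ratio of total reads (3 times the means) scaled by the size-factor ratio of the table. They and the floor cover counting error only, and reads are not independent molecules.

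The tables' gene models were 2112 in all, of which 0 matched an identifier in the reference gene table used here (assembly Cucumber_9930_V3), so names come only from the best-hit descriptions, often of proteins in other species, and no coordinates are printed. Informative descriptions were present for 45.3%, 37.3% and 32.2% of entries at 2, 6 and 12 h. The counts of gene lists can thus be too low, and through chance matches of words also too high. By their identifiers, 2 entries at 6 h and 3 at 12 h were further models of a locus already listed, and each was counted as a gene. Before the data were examined, 40 gene lists were fixed as word patterns over descriptions, together with the tests, the alternatives not marked otherwise and the rule for named genes. That rule takes, per time point, the 8 largest and 8 smallest log2 ratios among genes with an informative description, above 0 in both groups and with 10 or more normalized counts in the higher group, then for each list with 3 or more listed members the higher and the lower member of smallest FDR, and the 10 genes listed at all 3 time points with the largest change at 12 h. Genes without an informative description that this last part selects are not described singly. Genes named outside the rule were chosen after their values were seen, whether or not their sentences repeat it. The pattern for clock genes also matched the letters lux in efflux: 5 of its 6 members at 12 h are auxin and MATE efflux genes, so the list was not interpreted. Likewise a DELLA protein entered the vascular markers through its description, and the words of the cucurbitacin list matched a trypsin inhibitor of the genus Cucurbita.

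The direction of each list was tested by a two-sided Fisher's exact test of higher and lower members against the other genes of the same table, with Benjamini-Hochberg adjustment over 83 tests. Over-representation among higher or lower genes was tested likewise against all genes in any of the 3 tables (228 tests), the alternative fixed for unmatched identifiers. Genes that changed by less than 2-fold are missing from this background, and a count adjusted over the list alone could not be formed because unlisted members have no p-value here. Time of appearance was tested for 38 lists. All these tests treat genes as independent draws, which they are not, and hold no spread between replicates. Overlaps are given with exact binomial intervals, with the product of list sizes over the number of genes, and with 100 simulated draws of 2 unchanged time points against 3 shared controls, using spreads back-calculated from the p-values. The list test was tested on simulated data: among 40 lists of 15 genes, 5 of 5 lists with 14 genes in the rarer direction were recovered and 0 of 35 random lists called, both at 730 genes (6 h) and at 1773 genes (12 h). With all 15 genes in the commoner direction 5 of 5 were recovered too, with 0 of 35 random lists called at 6 h and 2 of 35 at 12 h. The smallest p of those skewed lists at 12 h was 0.00181 (Fisher's exact test), so that a list leaning the commoner way can miss the correction over 83 tests when few others lean. Alternatives were stricter thresholds, removal of low-abundance genes and of genes at 0, removal of genes in several lists and, chosen after the data were seen, wider word patterns for 7 lists and subsets by size of change. The work used Python 3.11.15, SciPy 1.17.1, pandas 2.3.3, NumPy 2.4.6 and Matplotlib 3.10.9.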

Results

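RNA was sequenced from leaves of cucumber seedlings (Cucumis sativus, strain Cu-01) taken before chilling and after 2, 6 and 12 h in dark air held at 6 °C. Each of the 4 time points had 3 libraries, called biological replicates in the labels, which gave 12 libraries in all. The series text calls the raw data files of 3 libraries corrupted, and whether these libraries entered the deposited means and tests is not given in the sources used here. Multiplied by 3, the mean read counts at 0 h were whole in 100% of entries, as sums over 3 libraries are. The 3 tables used here compare each chilled time point with 0 h, hold the authors' mean over the 3 libraries of each group, and list only genes with a change of at least 2-fold (an absolute log2 ratio of 1) and a false discovery rate (FDR) under 0.001. Values of single libraries and the total depth of each library were not analysed here, so no spread between replicates is given. The FDR rests on that spread only as the authors' test estimated it, and does not measure it. Median mean read counts of the listed genes in the 0 h libraries were 111 in the 2 h table, 241 in the 6 h table and 215 in the 12 h table. Gene names are those of the best database hits given in the tables, and the genome positions of the genes were not given in the sources used here.

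The number of listed genes grew with the time in the cold, and the balance of directions turned over. At 2 h, 86 genes were listed, 53 of them higher and 33 lower than at 0 h. At 6 h the list held 730 genes, 461 higher and 269 lower, and at 12 h it held 1773 genes, 639 higher and 1134 lower. Higher genes thus made up 61.6% of the list at 2 h (95% exact binomial interval 50.5 to 71.9%), 63.2% at 6 h (59.5 to 66.7%) and 36.0% at 12 h (33.8 to 38.3%). These intervals treat genes as independent draws, which they are not, and hold no spread between replicates and no error of scaling. Among genes with an absolute log2 ratio of 2 or more, the split at 12 h was closer to even, with 243 higher and 263 lower. A uniform downward shift of the 12 h ratios by the authors' scaling would also lower the share of higher genes, and cannot be told apart here.

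**Figure D1:**
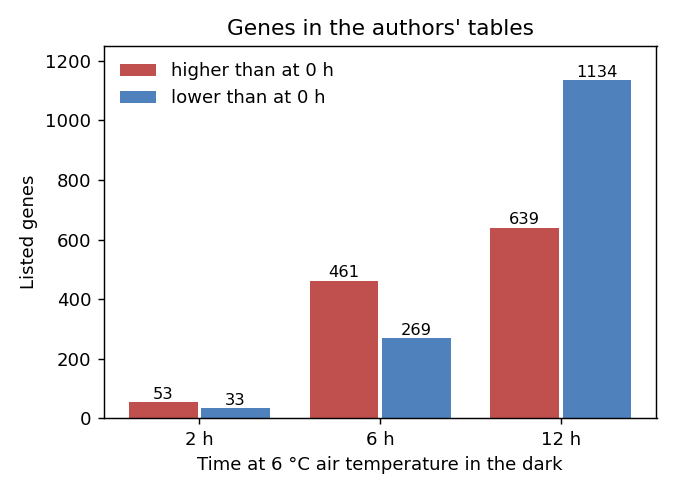
Bars give the number of genes listed by the authors as higher (red) or lower (blue) than at 0 h, by hours of chilling. Higher genes outnumbered lower ones at 2 h (53 and 33) and 6 h (461 and 269), and lower genes outnumbered higher ones at 12 h (1134 and 639).

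The comparison of 2 h with 0 h asked which transcripts changed soon after the leaves were put in the cold. Of the 8 named genes with the largest increases, 4 were transcription factors. A gene described as CRT/DRE binding factor (Csa3M180260.1), the family that activates cold-regulated genes through the C-repeat element, went from a mean of 249 to 1025 reads per library, a log2 ratio of 2.02 in the authors' deposited table. All 3 listed AP2/ERF domain factors, a family of ethylene- and stress-responsive regulators, were higher in the authors' deposited table, Csa7M047400.1 with a log2 ratio of 2.39, Csa3M207390.1 with 2.37 and Csa5M150420.1 with 1.02. The lower genes included a SAUR family protein (Csa2M258630.1) at -1.61 and a gibberellin-regulated protein (Csa3M826660.1) at -1.15 in the authors' deposited table. The other gibberellin gene listed at 2 h, a gibberellin 20-oxidase (Csa5M052540.1, named after its values were seen), a synthesis enzyme, was higher with 1.46 in the authors' deposited table.

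Other regulators went both ways at 2 h. A DOF domain transcription factor (Csa1M039960.1) had the largest log2 ratio of the named genes in the authors' deposited table, 4.22, but from a mean of only 2.67 reads at 0 h, so that counting error alone leaves a 95% interval of 3.16 to 5.42. WRKY transcription factor 5 (Csa3M710870.2) had a log2 ratio of 1.34 and the calcium dependent protein kinase 24 (Csa4M011740.1), from a mean of 7 reads at 0 h, one of 2.21 in the authors' deposited table, while another calcium-dependent protein kinase (Csa6M439940.1, named after its values were seen), from a mean of 132 reads, had -1.02. The list of CBF/DREB cold regulators held 1 listed gene, DREB1F (Csa5M155570.1, a gene named after its values were seen), with 1.51 in the authors' deposited table, since the description of the CRT/DRE binding factor does not match its words. Nitrate reductase (Csa4M377160.1), which turns nitrate into nitrite, had 1.78, and the late-embryogenesis-type protein ECP63 (Csa3M748200.1) 1.98 in the authors' deposited table. Among the lower genes, the authors' deposited table gave -1.37 for a C3HL domain factor (Csa6M191570.1), -1.11 for a cyclin-dependent protein kinase (Csa3M127030.1) and -1.07 for xyloglucan endotransglucosylase/hydrolase 1 (Csa6M423390.1), a cell wall enzyme. With 3 of 3 AP2/ERF members higher against 60.2% of the other genes listed at 2 h (two-sided Fisher's exact test, p = 0.282, adjusted p = 0.916 over 83 tests of lists and time points), the list was too small for any lean to higher genes to pass. The other lists had at most 2 members at 2 h, too few to set them apart from the rest.

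The comparison of 6 h with 0 h asked the same after a longer exposure. Genes of phenylpropanoid synthesis, the pathway from phenylalanine to lignin and flavonoid precursors, were mostly higher, 14 of the 15 listed members. Of these, 10 were described as phenylalanine ammonia-lyase, the entry enzyme of the pathway, with log2 ratios from 1.19 to 1.91 in the authors' deposited table, and phenylalanine ammonia-lyase 2 (Csa6M445780.1) went from a mean of 2210 to 7482 reads. The cold regulator CRT/DRE binding factor reached a log2 ratio of 3.11, and WRKY transcription factor 5 reached 3.46, in the authors' deposited table. In the auxin response list, 7 of the 8 listed members were lower. The list is matched by words, and its lower members include an auxin-repressed protein and an auxin efflux facilitator. Its count therefore does not measure the response to auxin. Expansin 2 (Csa6M014540.1), a wall-loosening protein, fell from a mean of 13634 to 2655 reads, a log2 ratio of -2.21 in the authors' deposited table.

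The other phenylpropanoid members higher at 6 h were the pair of 4-coumarate coenzyme A ligases (Csa7M430250.1 and Csa7M430240.1), with 2.81 and 2.74, and the pair of cinnamoyl-CoA reductases (Csa3M716370.1 and Csa3M716870.1), with 1.46 and 1.35 in the authors' deposited table, these 4 being named after their values were seen. The lower member was an anthocyanin acyltransferase (Csa7M343340.1), at -1.53 in the authors' deposited table. Among genes in any of the 3 tables, 14 of 18 members of the list (77.8%) were higher at 6 h, against 21.3% of other genes (two-sided Fisher's exact test, p = 6.02e-07, adjusted p = 0.000137 over 228 tests). Their direction among the genes listed at 6 h had p = 0.0135 in the same exact test and did not pass the correction (adjusted p = 0.224). The ammonia-lyase gene models can share reads if they are near-identical copies, so that their 10 values are uncertain singly, and without them the over-representation had an exact p of 0.0703 (4 of 8 members). With absolute log2 ratios of 2 or more, only 3 members of the list were left, 2 of them higher at 6 h, and the over-representation did not pass (exact p = 0.0801).

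Signalling genes at 6 h included the respiratory burst oxidase-like gene Csa3M845500.1, whose product makes superoxide, with 1.65, a protein phosphatase 2C (Csa1M532300.1), a class that acts in abscisic acid signalling, with 1.61, and a BRI1-associated receptor kinase 1 precursor (Csa3M850580.1) with 1.65 in the authors' deposited table. All 4 listed WRKY genes were higher, among them the abundant WRKY transcription factor 30 (Csa3M119700.1), at 1.45 from a mean of 12759 reads at 0 h in the authors' deposited table. Hormone metabolism moved in both directions. The authors' deposited table gave -3.26 for 9-cis-epoxycarotenoid dioxygenase (Csa6M523440.1), the key step of abscisic acid synthesis, and -1.74 for gibberellin 3-oxidase (Csa7M434970.1), which makes active gibberellins. Of the pair of gibberellin 2-oxidases, which inactivate gibberellins, Csa4M075200.1 had 1.48 and Csa1M439830.1 had -1.28 in the authors' deposited table. Of the pair of ACC synthases, which make the ethylene precursor, Csa6M496450.1 had -3.13 and Csa1M580750.1 had 2.45 there, both from means under 30 reads at 0 h, with Csa1M439830.1 and Csa1M580750.1 named after their values were seen. In auxin response, the auxin efflux facilitator Csa5M576590.1 had -1.25, an auxin-repressed protein (Csa6M518000.2) had -2.97 and the amido synthetase GH3.3 (Csa6M492310.1), which conjugates auxin to amino acids, had 1.26 in the authors' deposited table. The 1 of 8 higher share of this list, against 63.7% of the other genes listed at 6 h, had p = 0.0048 in Fisher's exact test and an adjusted p of 0.117.

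Cell wall and transport genes also went both ways at 6 h. Of 16 cell wall members, 10 were higher and 6 lower (Fisher's exact test, p = 1, adjusted p = 1), and the authors' deposited table gave 2.17 for the xyloglucan endotransglycosylase Csa1M422990.1 beside the expansin 2 value above. In the list of ion, water and nitrogen transport, 4 of 11 members were higher (exact p = 0.11, adjusted p = 0.916). The ammonium transporter Csa6M507360.1 had 3.24 and another ammonium transporter (Csa2M079100.1) -1.19 in the authors' deposited table. The aquaporin model Csa6M445140.2 had -4.42 there from a mean of 16 reads at 0 h and 0.667 at 6 h, and counting error alone spans -7.52 to -2.51. A ferulate-5-hydroxylase (Csa4M043910.1, named after its values were seen) was at 0 reads at 0 h and at a mean of 21.7 at 6 h. That is 23.9-fold higher when 3 reads over the 0 h group are taken as the floor.

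The comparison of 12 h with 0 h covered the longest exposure. All 16 listed members of the auxin response list were lower, with a median log2 ratio of -2.59. Of these, 8 were SAUR family proteins, small auxin-induced proteins of growing tissue, with log2 ratios from -6.00 to -1.87 in the authors' deposited table. Auxin efflux facilitators are also in this word-matched list, so its count does not measure the response to auxin. Lower genes also prevailed in the lists of cytochromes P450 and glycosyltransferases (23 of 25), ubiquitin ligases and protein turnover (12 of 12) and MYB factors (9 of 9). Among named genes with reads in both groups, the largest increase was that of the ammonium transporter Csa6M507360.1, from a mean of 41.7 to 6125 reads, a log2 ratio of 7.34 in the authors' deposited table. Heat shock protein 70 (Csa4M295440.1), a protein-folding chaperone, went from a mean of 17729 to 62067 reads, a log2 ratio of 1.93 in the authors' deposited table, and catalase isozyme 1 (Csa4M658590.1), which breaks down hydrogen peroxide, fell from 115391 to 51499 reads, a log2 ratio of -1.04.

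Over the 16 auxin members, the lower share had an exact p of 0.00102 in Fisher's test against the other genes listed at 12 h, of which 36.4% were higher, and an adjusted p of 0.085 over the 83 tests. With wider word patterns, chosen after the data were seen, 18 of 18 members were lower (exact p = 0.000655, adjusted p = 0.0275). The members added in this way were picked with their values known, so that count is no independent evidence of a direction. As over-representation among lower genes, with 16 of 17 members against 53.4% of other genes, the same list passed the correction (Fisher's exact test, p = 0.000425, adjusted p = 0.0484). That call ended with absolute log2 ratios of 2 or more (10 of 10 members, exact p = 0.000459, adjusted p = 0.0771), without genes in several lists (13 of 14, adjusted p = 0.141), where the 3 members left out were auxin efflux facilitators that the clock list holds only through a chance match of letters, and in the upper 3 of 4 parts of genes by abundance (7 of 7, adjusted p = 0.399). The SAUR proteins Csa4M556180.1 and Csa6M137590.1 had -5.07 and -4.72 in the authors' deposited table, and the auxin efflux facilitator Csa5M284520.1, a carrier that moves auxin out of cells, had -1.18. SAUR gene models Csa7M009130.1 and Csa7M009070.1 had -6.00 and -5.52 there, but each rested on a mean of 0.333 reads at 12 h, with counting intervals of -11.26 to -3.41 and -10.76 to -2.88. For cytochromes P450 and glycosyltransferases the exact p was 0.00254 (adjusted p = 0.105), for ubiquitin ligases and protein turnover 0.00566 (adjusted p = 0.117) and for MYB factors 0.0309 (adjusted p = 0.427), so that none of these directions passed the correction. With the wider word patterns, the ubiquitin list had 17 lower and 2 higher members of 19 (exact p = 0.0275, adjusted p = 0.288). Of the 83 direction tests, 7 had an unadjusted exact p under 0.05 and 0 an adjusted one. Examples in the authors' deposited table were cytochrome P450 77A3 (Csa6M044530.1) at -1.48, the E3 ubiquitin ligase PUB14 (Csa2M354770.1) at -1.51, the EIN3-binding F-box protein 4 (Csa2M006790.1), which acts in ethylene signalling, at -1.48, and a MYB domain factor (Csa3M826690.1) at -1.04.

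Several transcription factor and signalling lists, though not the MYB list, had members that went both ways at 12 h. The AP2/ERF list had 5 higher and 4 lower members (exact p = 0.297, adjusted p = 0.916), with RAP2 (Csa6M091830.1) at 1.76 and an ethylene-responsive element-binding protein (Csa7M049230.1) at -1.57 in the authors' deposited table. With wider word patterns, chosen after the data were seen, 10 of 17 AP2/ERF members were higher at 12 h (exact p = 0.0724, adjusted p = 0.608). An AP2 domain factor (Csa7M432080.1), outside the fixed list by its description, had the lowest log2 ratio of the named genes in the authors' deposited table, -7.23. It went from a mean of 61.7 reads at 0 h to 0.333, with a counting interval of -12.72 to -4.91. WRKY transcription factor 30 had 1.27 and WRKY transcription factor 21 (Csa4M051470.1) -2.07 in the authors' deposited table. Of 10 calcium signalling members, 6 were higher (exact p = 0.183, adjusted p = 0.916). Wider word patterns, chosen after the data were seen, added 10 members, all higher and glutamate receptors among them, so the count of 16 of 20 is no independent evidence of a direction. The CBL-interacting kinases, which act with calcium sensors, went both ways in the authors' deposited table, Csa2M009490.1 at 1.38 and Csa1M269880.1 at -1.12. Of 6 gibberellin members, 5 were lower (exact p = 0.428, adjusted p = 0.946). The higher member, the DELLA protein GAIP (Csa7M372280.1), a repressor of gibberellin response, went from 0 reads at 0 h to a mean of 17.3 at 12 h. That is 18.8-fold over a floor of 3 reads in the group, and the counting interval reaches down to a log2 ratio of 3.89. The CBF/DREB list had 1 higher and 1 lower member (exact p = 1), CBF/DREB1 transcription factor 2 (Csa5M174570.1) with a log2 ratio of 2.24 and a DREB-like protein (Csa2M374590.1) 2.82-fold lower in the authors' deposited table, both named after their values were seen. The CRT/DRE binding factor, at 2.96 there, is outside this list by its description. With wider word patterns, chosen after the data were seen, 2 of 3 members were higher. The cytokinin response regulator ARR8 (Csa5M434550.1) had -2.99, and the NAC domain genes Csa7M353010.1 and Csa6M139190.1 had 2.08 and -2.24 in the authors' deposited table.

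Metabolism, transport and wall genes at 12 h showed large changes in single members. The authors' deposited table gave 5.01 for a cation proton exchanger (Csa1M025970.1), 5.96 for a lipid binding protein (Csa3M146480.1), 2.07 and -2.49 for triacylglycerol lipases (Csa7M407550.1 and Csa1M537320.1), and 1.85 and -1.72 for sugar transporters (Csa6M424530.1 and Csa2M245410.1). Of 23 cell wall members, 6 were higher and 17 lower (exact p = 0.386, adjusted p = 0.916), with 3.14 for the xyloglucan endotransglycosylase Csa1M422470.1 and -3.06 for expansin 2 in the authors' deposited table. Of 14 redox members, 8 were higher (exact p = 0.159, adjusted p = 0.916). In the phenylpropanoid list, 3 of 6 members were higher (exact p = 0.673, adjusted p = 1), with phenylalanine ammonia-lyase 2 at 1.36 and chalcone synthase (Csa3M600020.1), the entry enzyme of flavonoid synthesis, at -1.48 in the authors' deposited table. Of 3 ammonia-lyase genes at 12 h, 2 were higher and 1 lower. The lower one (Csa6M405960.1, named after its values were seen), at -1.51 there, is outside the list because its description is spelled differently. All 4 listed phloem and vascular marker genes were lower at 12 h (exact p = 0.303, adjusted p = 0.916), among them the phloem protein 2 gene ATPP2-A13 (Csa5M173520.1) at -2.38 in the authors' deposited table and another DELLA protein (Csa5M569350.1, named after its values were seen) at -1.19. No gene of the photosystem list or of the guard cell, trichome and epidermis list was among those listed at any time point, which says only that none passed the authors' filter under these names.

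**Figure D2:**
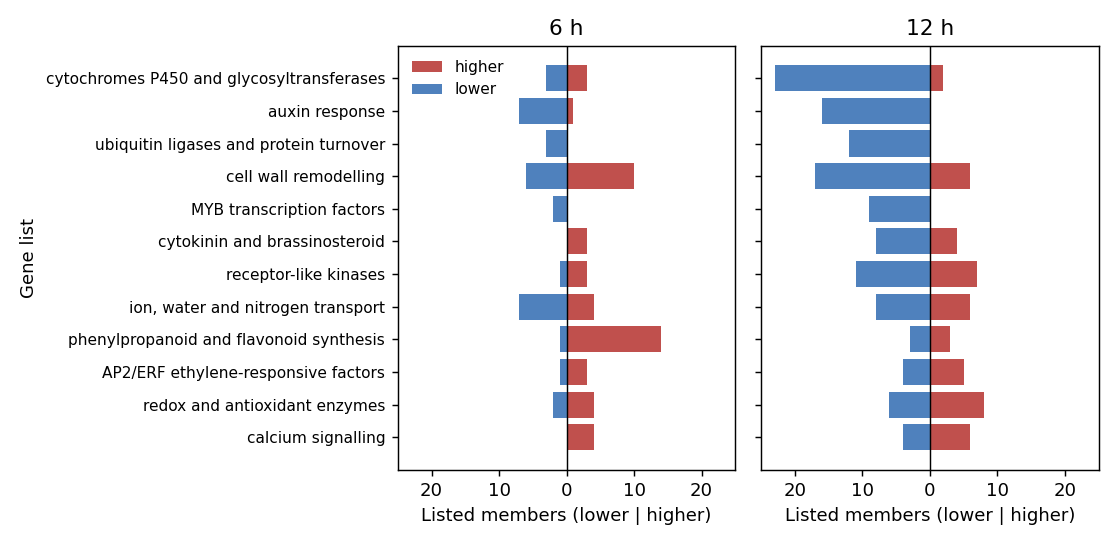
Bars give the number of listed members of 12 gene lists that were higher (red, to the right) or lower (blue, to the left) than at 0 h, at 6 h in the left panel and 12 h in the right panel, for lists with 8 or more members at either time. Phenylpropanoid genes numbered 14 higher and 1 lower at 6 h, cytochromes P450 and glycosyltransferases 2 higher and 23 lower at 12 h, and auxin response 0 higher and 16 lower at 12 h, where 64.0% of all listed genes were lower, and none of these directions passed the correction.

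The overlap between time points asked whether genes listed early were listed again. Of the 30 genes listed at all 3 time points, 24 were higher and 5 lower throughout, and Dof23 (Csa6M338090.1, named after its values were seen) was higher at 2 and 6 h and lower at 12 h. The 24 included the CRT/DRE binding factor, at 2.02, 3.11 and 2.96 after 2, 6 and 12 h in the authors' deposited tables, the AP2/ERF factor Csa7M047400.1 at 2.39, 3.22 and 2.92, WRKY transcription factor 5 at 1.34, 3.46 and 4.05, and ECP63 at 1.98, 3.38 and 3.17. The SAUR protein Csa2M258630.1 had -1.61, -2.55 and -2.57 in the authors' deposited tables.

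Of the genes listed at 2 h, 41.9% were listed again at 6 h and 53.5% at 12 h. Of those listed at 6 h, 58.2% were listed again at 12 h. Among the shared genes only, those of 2 h had the same direction in 36 of 36 cases at 6 h (100%, 95% exact binomial interval 90.3 to 100%). At 12 h they had it in 41 of 46 cases (89.1%, 76.4 to 96.4%). Between 6 and 12 h, 425 genes were shared and 415 of them had the same direction (97.6%, 95.7 to 98.9%), 220 higher and 195 lower. Independent lists drawn from the 2112 genes in any table would share 139 higher and 144 lower genes, and drawn from the 20290 genes tested 14.5 higher ones. Simulated time points without any effect shared at most 0 listed genes in 100 draws, which gives no chance value for changed genes, because almost no gene passes the filter without an effect. The 3 comparisons use the same 0 h libraries, which could not be split here, so part of the overlap can come from them. The binomial intervals treat genes as independent draws and leave this out.

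**Figure D3:**
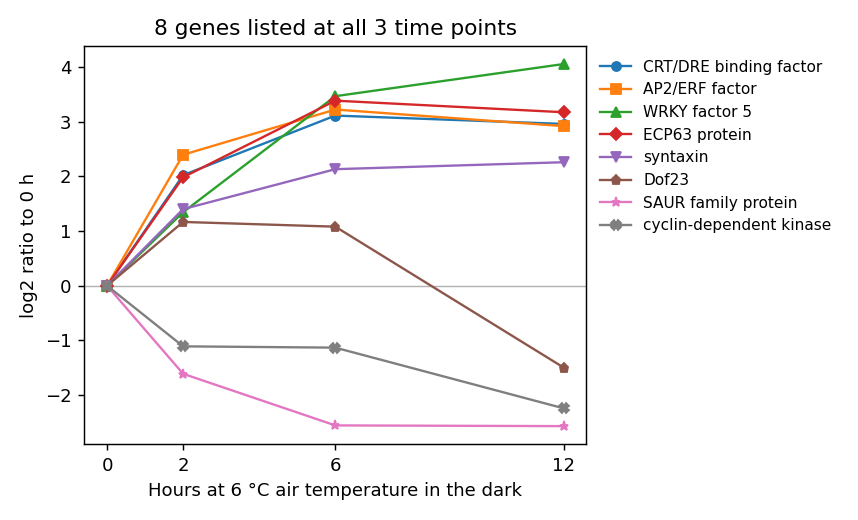
Lines join the authors' log2 ratios to 0 h (vertical axis) of 8 genes at 2, 6 and 12 h of chilling (horizontal axis, hours), with 0 h set to 0 by definition. Of the 8 genes, 5 stayed above 0, 2 stayed below 0, and Dof23 (Csa6M338090.1) went from 1.08 at 6 h to 2.82-fold lower at 12 h.

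The comparison of 12 h with 6 h asked whether changes grew in the genes listed at both. Of the genes lower at both times, most were lower still at 12 h, 159 of 195 (81.5%), with a median change of -0.47 in log2 ratio. Of the genes higher at both, 130 of 220 (59.1%) were higher still at 12 h, with a median change of 0.10 (two-sided Fisher's exact test of the shares, p = 7.17e-07). The test treats genes as independent draws, which they are not, and holds no spread between replicates. The shares and median changes leave out the 234 of 461 higher and 71 of 269 lower genes of 6 h that were absent at 12 h. The contrast in shares could also come from a uniform downward shift of the 12 h ratios by the scaling, which cannot be told apart. With absent genes ranked as furthest back, genes with a log2 ratio of 2 or more at 6 h had a median change of -0.29 (95% interval -0.51 to -0.09), and genes with -2 or less had one of 0.09 (-0.35 to 0.72). Growing changes included the ammonium transporter Csa6M507360.1, from 3.24 to 7.34, and the SAUR protein Csa4M556180.1, from -1.91 to -5.07 in the authors' deposited tables. Phenylalanine ammonia-lyase 2 went the other way, from 1.91 to 1.36 in the authors' deposited tables. Over the 425 genes, the median change away from 0 among those with the same direction was 0.25. Without genes at 0 reads in either group, whose ratios rest on the value written for 0, 422 genes remained. Across these genes, which are not independent replicates, Pearson's r was 0.926 and Spearman's rho 0.880 over both directions. Within the higher genes r was 0.769 and rho 0.628, and within the lower genes 0.599 and 0.489. The covariance was 4.24 over these listed genes and 0.0464 over all genes of simulated time points that share only the controls (correlation 0.499). These covariances cannot be set against each other, because listing at 2-fold or more itself widens the first.

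**Figure D4:**
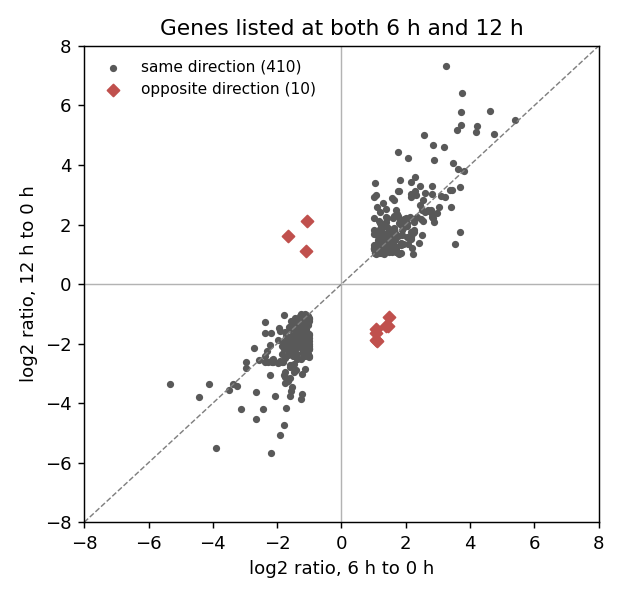
Each point is a gene listed at both times, with the authors' log2 ratio to 0 h at 6 h on the horizontal and at 12 h on the vertical axis, both linear and limited to 8, which leaves out 5 genes, and the dashed line marks equal ratios. Points for 410 genes with the same direction lie in 2 quadrants and 10 diamonds mark genes with opposite directions.

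The time of appearance asked which gene lists changed before 12 h. Phenylpropanoid genes appeared early, with 15 of 18 listed members (83.3%) first listed at 2 or 6 h against 36.5% of other genes (two-sided Fisher's exact test, p = 6.94e-05, adjusted p = 0.00264 over 38 lists). These 15 are the members listed at 6 h, so the result largely restates their over-representation there and is no separate evidence. With absolute log2 ratios of 2 or more no list passed (smallest adjusted p = 0.375 in the same exact test). Without the ammonia-lyase genes, which can share reads, 5 of 8 members appeared early (exact p = 0.151). Cell wall genes, with 17 of 30 members appearing by 6 h, had an exact p of 0.0344, and ion, water and nitrogen transport genes, with 11 of 18, one of 0.0471, and neither passed the correction (adjusted p = 0.533 for both). Of 29 cytochromes P450 and glycosyltransferases, 6 appeared by 6 h (exact p = 0.0811, adjusted p = 0.533). The cold treatment, the time in darkness and the time of day passed together in this design, so the comparisons with 0 h cannot separate them.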

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

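The tests of explanations in this part were chosen only after the result was seen.

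Between 6 and 12 h, 10 genes turned from higher to lower or the reverse, and between 2 and 12 h 5 genes did. These stood out because the effect of chilling had opposite signs at 2 time points. The difference itself was not tested on single libraries. From higher at 6 h to lower at 12 h went cytochrome P450 88D3 (Csa3M903540.1, with log2 ratios of 1.09 and -1.89 in the authors' deposited tables), Dof23 (Csa6M338090.1, 2.11-fold higher and then 2.82-fold lower), a ribosome-inactivating protein (Csa5M428440.1, 2.64-fold higher and then 2.65-fold lower) and a gene similar to PDF (Csa6M178950.1, 2.71-fold higher and then 2.64-fold lower), all named after their values were seen. From lower to higher went a glutamate-gated channel subunit GluR5 (Csa2M357240.1), at -1.08 and 2.13 in the authors' deposited tables. The other 5 genes had no informative description. Of the 5 genes that turned between 2 and 12 h, Dof23 was again the 1 with an informative description.

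Counting error at low read numbers was argued against: the reads at 6 and 12 h, at least 67 in total per gene and time, differed with an exact binomial p of at most 7.13e-68 after multiplying by the 20368 genes tested, which allows for the choice of these genes but not for spread between replicates. An untypical level in the shared 0 h libraries cannot be told apart from a reversal, because the smallest fold between chilled means at 6 and 12 h, 4.64, was set by picking genes 2-fold or more from 0 h in opposite directions. A response that reverses with the length of chilling stays open as a hypothesis, and so does a change with darkness or time of day, which passed together with chilling.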

How the results depend on the processing

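No paired analysis was possible because the tables hold group means and no column of a single library; for the same reason leave-one-out fits, a replicate block, count-based tests and another pseudocount were not run, nor was over-representation against the reference genes, whose identifiers did not match. Limits of FDR under 0.01, FDR under 0.001 and absolute log2 ratio of 1 remove no listed gene and so test nothing. Of the remaining alternatives, wider word patterns and all settings of the genes absent at 12 h were chosen after the data were seen. With an absolute log2 ratio of 2 or more, listed genes numbered 10 at 2 h (9 higher, 1 lower), 139 at 6 h (98 and 41) and 506 at 12 h (243 and 263); the shared genes of the same direction were 6 for 2 and 6 h, 3 for 2 and 12 h and 87 for 6 and 12 h; and 0 lists passed over-representation (3 at an unadjusted exact p under 0.05) and 0 the time of appearance (1 unadjusted), in each case with fewer genes. Among the upper 3 of 4 parts by abundance, 21 genes were lower at 2 h. Over-representation passed for 1 list, in place of 2, both in the upper 3 of 4 parts by abundance and without genes in several lists. With wider word patterns, 2 list directions passed in place of 0: auxin response at 12 h (0 of 18 higher, Fisher's exact test, adjusted p = 0.0275) and calcium signalling at 12 h (16 of 20 higher, adjusted p = 0.00578). The calcium call rests on 10 members added after the data were seen, all higher, and is no evidence of a direction. The auxin call likewise passed only with members added after the data were seen, all lower, and is no independent evidence. The share absent at 12 h among genes higher at 6 h exceeded that among lower ones by 24.4 percentage points, and among genes with an absolute log2 ratio of 2 or more the difference was -0.921 points (exact p = 1). For phenylpropanoid genes against other higher genes that excess was 36.0 points, and without ammonia-lyase genes 50.3 points with an exact p of 0.123 on 4 genes. Over all results, 96 alternatives gave the same call or a count within 1.5 times, while 18 moved further, 1 was weaker, 1 stronger and 1 reversed. Among the 96 are the limits that remove no gene. They also include total counts in the upper 3 of 4 parts by abundance, which stay within 1.5 times by construction. The number 96 is therefore no measure of robustness. The cause of the other changes was not tested. Reads limit precision, with an approximate standard error of 0.366 (log2) below a mean of 100 reads at 12 h and 0.0660 from 1000 reads on.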

Other observations

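The tests of families and of explanations in this part were chosen only after the results were seen, and so was the test of genes absent at 12 h.

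Some families picked by eye went one way at 12 h. The 5 listed genes described as syntaxin, synaptosomal associated or synaptobrevin-related protein, which act in vesicle fusion, were all higher, with log2 ratios from 1.29 to 2.26 in the authors' deposited table. The syntaxin Csa3M779010.1 had 2.13 and 2.26 after 6 and 12 h in the authors' deposited tables, from a mean of 1143 reads at 0 h. All 7 listed glutamate receptor genes, which encode cation channels, were higher at 12 h, with 1.21 to 2.13 in the authors' deposited table. Because these families were picked for members that went one way, their direction tests (exact p = 0.000773 for the receptors and 0.00602 for the fusion proteins, adjusted p = 0.0240 and 0.0622 over 31 tests) are descriptions and no evidence for the families. Several receptors have neighbouring identifiers and can share reads.

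Values of other families, picked in the same way, follow. Ammonium transporters had 1 higher and 3 lower members at 12 h, with Csa6M507360.1 at 7.34 and Csa2M163170.1, from a mean of 12381 reads at 0 h, at -1.24 in the authors' deposited table. The 4 listed xyloglucan endotransglycosylases were higher at 12 h (1.13 to 3.14) while all 8 listed expansin gene models were lower (-3.06 to -1.23) in the authors' deposited table, both families being wall-modifying proteins, and neither direction passed over the 31 tests (exact p = 0.0168 and 0.0569, adjusted p = 0.0939 and 0.196). The expansin models Csa1M522540.1 and Csa1M522540.2 carry the identifier of 1 locus, which was thus counted more than once. The 4 genes described as FOM-2 or R-FOM-2, a Fusarium resistance gene of melon, were lower at 12 h, with -1.36 to -1.24 in the authors' deposited table (exact p = 0.303, adjusted p = 0.523). Catalase genes differed too, with isozyme 1 at -1.04 and a catalase-1/2 entry (Csa4M658600.1) at 1.76 in the authors' deposited table. Actin (Csa7M056470.1), from the list of housekeeping genes, was higher at 6 h with 1.02 in the authors' deposited table.

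Genes higher at 6 h were more often absent from the 12 h table (234 of 461, 50.8%) than genes lower at 6 h (71 of 269, 26.4%, Fisher's exact p = 8.47e-11). Higher genes lying closer to the 2-fold limit was argued against: within 9 bands of log2 ratio the difference was 25.5 percentage points (permutation p = 0.0001, the smallest that 10000 permutations can give). Fisher's test and the permutations treat genes as independent draws, which they are not, and hold no spread between replicates. A uniform downward shift of the 12 h ratios by the scaling may contribute and cannot be told apart, because with log2 ratios of 2 or more in size at 6 h, absent genes ranked as furthest back, the median change was -0.29 in higher genes (95% interval -0.51 to -0.09) and 0.09 in lower ones (-0.35 to 0.72), intervals that overlap, though the shares absent were alike there (23.5% and 24.4%). With log2 ratios between 1.5 and 2 in size, where 47.5% of higher and 19.4% of lower genes were absent, the median change was -0.69 in 99 higher genes (upper limit -0.44) and -0.31 in 67 lower ones (-0.50 to -0.15), so both moved down. A transient response to cold was not tested apart from time in the dark.

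Phenylpropanoid genes were over-represented among genes higher at 6 h, and 12 of those 14 were absent at 12 h (85.7% against 49.7% of other higher genes, exact p = 0.0118, adjusted p = 0.130 over 11 lists, which did not pass). Reads shared among near-identical phenylalanine ammonia-lyase copies may have counted 1 change several times: without these genes the exact p was 0.0703 (4 of 8 members against 21.4% of other genes), and with them taken as 1 gene 0.0262, so this cannot be told apart on so few genes. Time in darkness or time of day cannot be told apart from chilling either, since 0 unchilled libraries were sampled after 0 h. A passing induction of the pathway by cold remains a hypothesis.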
